A study of Mus musculus with 18 samples.

How the data were processed

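The series holds 18 samples of mouse cortex. RNA sequencing covered 12 libraries from tdTomato-positive neurons sorted at postnatal day 5, 4 per group: WT layer 6, Tbr1 null layer 6 and WT layer 5. ChIP-seq covered 6 samples of CD1 cortex at postnatal day 2. Groups, layers and sequencing batches were taken from the labels: all layer 6 libraries are batch A, layer 5 replicates 1 and 2 batch B and replicates 3 and 4 batch C. Per the labels' protocols, about 25000 cells were sorted per sample and stranded, ribosome-depleted total RNA libraries were made from them.

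The gene counts deposited by the authors are whole reads per gene. Per the submitters' processing notes, Trim Galore 0.4.2, BWA 0.7.16a, MACS2 2.1.0, STAR 2.5.2b, HTSeq, bedtools and the build mm9 were used in the series, and the gene annotation and the strand setting of the counting are not given in the sources used here. All 24015 genes of the table entered the library totals, and 0 columns were left unmatched to a sample. A second table deposited by the authors holds whole-number scores for 14567 genes in 12 columns, all with a median of 23, so its values were equalised between libraries and rounded by steps not given in the sources used here. It was used only for the sign of called genes, as log2 of the score plus a pseudocount of 1: the sign was the same for 99.5% of 2063 genes called between null and WT layer 6 and for 97.2% of 12471 called between layers. In that table Tbr1 has mean scores of 98.2 in null layer 6, 187 in WT layer 6 and 50.2 in WT layer 5.

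Each peak list deposited by the authors gives a score, a fold enrichment (a ratio over the caller's background), a −log10 p and a −log10 q per summit, as MACS2 writes them, with coordinates in mm9. The peak names deposited by the authors state that no fragment model was built and name the replicate and its control, so peaks were called per replicate. Summits that share a region were merged into 1 region, and coordinates are printed counting from 1.

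Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group and the quasi-likelihood F-test on the 2 groups compared. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Null and WT layer 6, WT layer 5 and WT layer 6, and null layer 6 and WT layer 5 were compared. Mean CPM and SD over 4 libraries are on TMM-scaled library sizes within each comparison, so a group's mean differs slightly between comparisons. Library totals of 27465597 to 54899002 counts set the precision, and a gene counted as detected at 10 counts. On simulated counts with the libraries' means and sizes, the test recovered 64%, 86%, 98% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold between null and WT layer 6, with 12 false calls among 14475 genes. For layer 5 against layer 6 it recovered 76%, 92%, 100% and 100%, with 10 false calls among 14376 genes. For null layer 6 against layer 5 it recovered 66%, 88%, 100% and 100%, with 6 false calls among 14883 genes. That simulation took libraries as independent. With no effect and variation shared within pairs, the same test called a mean of 732 genes between null and WT layer 6 and 666 between layers (5 draws). The share of genes whose groups do not overlap was taken from the same draws, after the data were seen. In these draws libraries of a pair differed by sampling noise alone, which the real pairs exceeded, so the simulated shares may be too high.

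Lists for layer 6 corticothalamic, subplate and layer 6b, layer 5 subcerebral, callosal and upper-layer, glutamatergic synapse, GABAergic postsynapse, WNT signalling, axon guidance, voltage-gated ion channel, cadherin, autism risk, interneuron, astrocyte, oligodendrocyte lineage, microglia, vascular and blood, dividing progenitor, immediate early and sex-linked genes were fixed before the data were examined, as were the tests, their alternatives and the rule for naming genes. A list of 13 mitochondrially encoded genes had 0 members in the count table. Lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation, adjusted over 19 lists, beside camera with an estimated correlation and fry. Lists of 18 earlier-stage and 18 later-stage neuronal genes and of 15 Cajal-Retzius cell markers were added after values had been seen.

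The rule for named genes took Tbr1, the 10 highest and 10 lowest fold changes among called genes with a mean CPM of at least 5 and groups that do not overlap, and up to 4 members of each list with the smallest adjusted p, or 5 for the corticothalamic, subcerebral, subplate and WNT lists. Predicted genes were not named, and 1 gene that the rule gave is not reported here. The rule gave 92 genes for null against WT layer 6 and 96 for layer 5 against layer 6, and the 31 and 30 named in the text were picked from these by hand after their values were seen, with Crym, the 1 riser of its list, named as well. Neighbours of Tbr1 and Cajal-Retzius markers in the closing section were chosen after their values were seen.

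The shared control of the comparisons with WT layer 6 was simulated with unchanged groups, in 20 draws for fold changes and 5 for calls, and was split 2 and 2. The simulated covariance at a mean CPM of at least 5 was added after the data were seen. Overlaps of peak regions were computed with bedtools 2.31.1 at a minimum of 1 bp, with Wilson intervals and copies shifted by 50 to 500 kb, using Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9. Gene order around Tbr1 came from a RefSeq table of another build, GRCm38.p6, used only for which genes neighbour each other: 14538 of 14588 tested genes were placed, 13741 of them by symbol. Alternatives were DESeq2 1.42.0, other scalings and filters, a replicate block, a fold threshold, summed pairs, each replicate left out, split controls and stricter peak overlaps. Binding near called genes and motifs at peaks need an annotation and a genome of mm9, which were not used here, so they were left out.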

Results

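The study measured gene expression in sorted neurons of the mouse neocortex and binding of TBR1, a T-box transcription factor of deep-layer cortical neurons, to chromatin of whole cortex. For RNA sequencing, tdTomato-positive neurons were sorted from cortices at postnatal day 5, about 25000 cells per sample, in 3 groups of 4 libraries: wild-type (WT) layer 6, Tbr1 null layer 6 and WT layer 5. The sample labels describe the mutant as a layer 6 null, whereas the series design speaks of a constitutive null, so it is called null here. For chromatin immunoprecipitation followed by sequencing (ChIP-seq), cortex of CD1 mice, an outbred strain, was taken at postnatal day 2 and gave 6 samples: 2 with a TBR1 antibody, 2 inputs, 1 with IgG and 1 whose antibody label names a TBR1 blocking peptide although its title says IgG. The question put by the series title is how the dose of Tbr1 after birth affects the connectivity of layer 6.

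The RNA count table held 24015 genes. Library totals were 32982957 to 54899002 counts in WT layer 6, 41091165 to 47540669 in null layer 6 and 27465597 to 39703820 in WT layer 5. Nothing in the labels says that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Counts were closest within pairs of libraries. In WT layer 6 the chi-square statistic per degree of freedom was 3.26 to 5.18 within the pairs 1 with 2 and 3 with 4, and 10.9 to 19.9 across them. In null layer 6 the same pairs gave 9.003 to 10.8 within and 23.1 to 61.8 across. In WT layer 5 the pairs were 1 with 3 and 2 with 4, each spanning the sequencing batches B and C, with 1.33 to 1.4 within and 2.97 to 3.41 across. The codes in the labels of the layer 6 libraries share a digit within the same pairs, so a pair may share an animal or a pool, which the labels do not state. No pair agreed within sampling noise, and n = 4 counts libraries, not animals. Xist, the RNA that coats the inactive X chromosome, stood at 0.469 and 0.455 CPM (counts scaled by the library total) in WT layer 6 replicates 1 and 2 and at 291 and 289 CPM in replicates 3 and 4. Null layer 6 libraries had 260 to 300.1 CPM of Xist. WT layer 5 libraries had 39.1 to 40.6 CPM of Xist together with 113 to 127 CPM of Y-linked genes. The ribosomal RNA gene Rn45s took 0.489% ± 0.158 (SD, n = 4) of the counts in WT layer 6, 1.45% ± 0.918 (n = 4) in null layer 6 and 1.23% ± 0.0168 (n = 4) in WT layer 5.

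Tbr1 itself was lower in null than in WT layer 6 neurons. It was at 95.3 ± 2.47 CPM (SD, n = 4) in null and 177 ± 6.90 CPM (n = 4) in WT libraries, a log2 fold change of -0.89 ± 0.035 (SE) with an adjusted p of 8.53e-09 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Every null library was below every WT library, with 91.6 to 97.7 against 173 to 183 CPM before scaling. Which part of the gene the null allele lacks is not given in the sources used here, so whether the remaining reads lie inside it is open.

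In null libraries, 12 of 20 genes that mark layer 6 corticothalamic neurons and 6 of 11 subplate genes were lower. Of 19 genes of layer 5 subcerebral projection neurons, 8 were higher. Each library is a pool of sorted cells, so a changed share of a cell type and a change within cells were not told apart. Tle4, a corepressor of corticothalamic neurons, was at 102 ± 3.09 CPM in null and 208 ± 16.2 CPM in WT libraries (n = 4 each), a log2 fold change of -1.03 ± 0.050. The dopamine receptor gene Drd1a was 8.52-fold lower in null, at 2.06 ± 0.149 against 17.5 ± 2.69 CPM. Fezf2, a transcription factor that specifies subcerebral projection neurons, was at 114 ± 3.47 against 66.6 ± 3.02 CPM, a log2 fold change of 0.78 ± 0.039. Nefl, which encodes the light neurofilament subunit, was 2.88-fold higher in null, at 282 ± 29.5 against 98.1 ± 6.68 CPM. The edgeR adjusted p (Benjamini-Hochberg) of these 4 genes was 4.85e-08 or less. For the 31 genes picked by hand from those the naming rule gave, and for Crym, it was 0.0119 or less, and the libraries of the groups did not overlap. The rule took genes by a small adjusted p or by groups that do not overlap, so both traits follow from the choice.

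**Figure D1:**
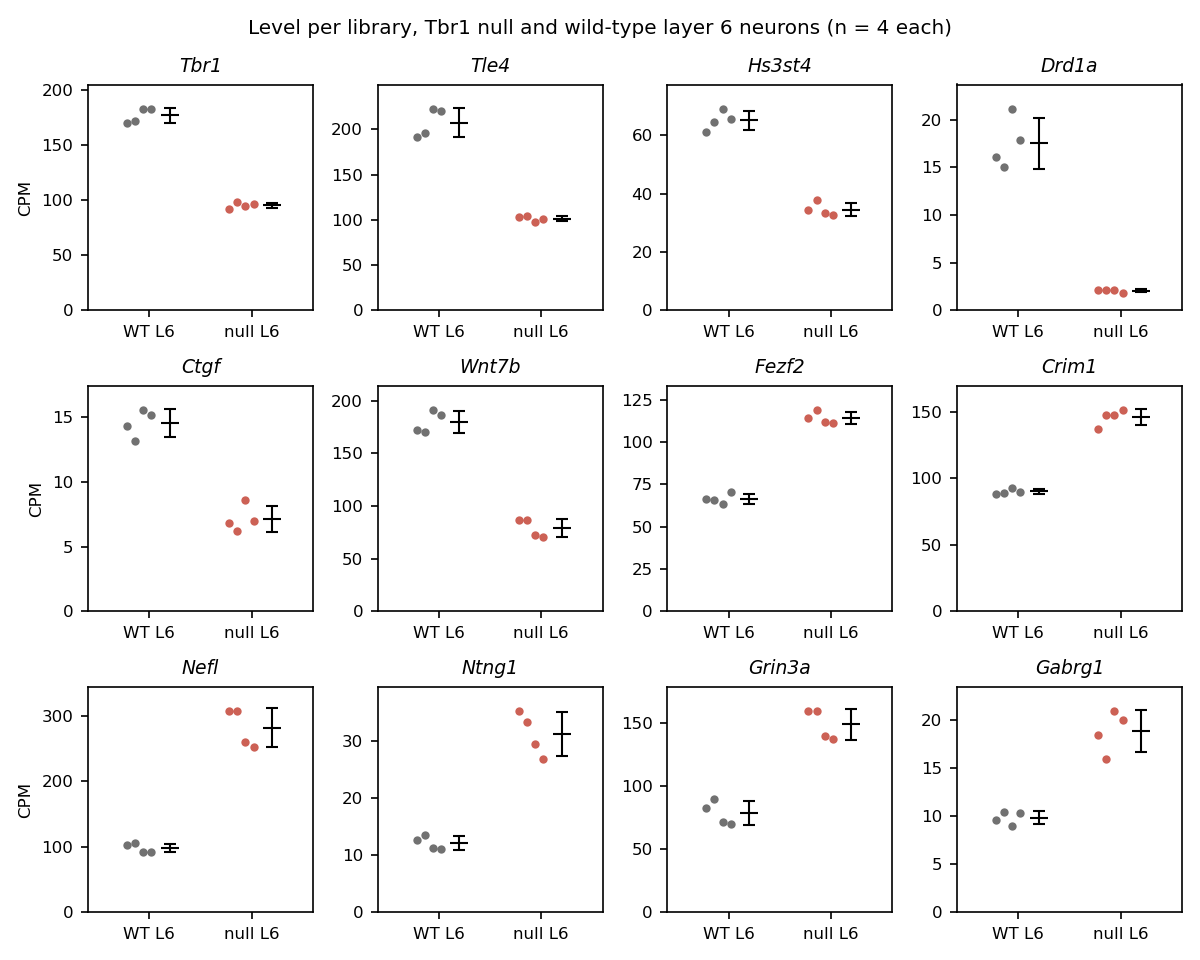
CPM of 12 genes in the 4 WT layer 6 and 4 null layer 6 libraries, 1 panel per gene, with points for libraries and a bar for the mean ± SD. Tbr1, Tle4, Hs3st4, Drd1a, Ctgf and Wnt7b are lower in every null library than in every WT library, and Fezf2, Crim1, Nefl, Ntng1, Grin3a and Gabrg1 are higher.

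Of the 20 measured layer 6 corticothalamic genes, 12 fell in null libraries, 1 rose and 7 were not called; adjusted over the list alone, 13 fell and 1 rose. The gene that rose was Crym, at a log2 fold change of 0.32 ± 0.075. Besides Tbr1 and Tle4, which are members, Hs3st4, a heparan sulfate sulfotransferase, fell with a log2 fold change of -0.92 ± 0.052. Of 11 subplate and layer 6b genes, 6 fell and 0 rose (7 and 1 adjusted over the list alone). They include Drd1a, the secreted matrix protein gene Ctgf at -1.03 ± 0.098 and the orphan nuclear receptor gene Nr4a2 at -0.68 ± 0.072. The camera test, with a preset correlation and Benjamini-Hochberg adjustment over 19 lists, gave adjusted p = 2.36e-09 for the corticothalamic list and 1.97e-05 for the subplate list. Both were called with an estimated correlation too, at adjusted p = 0.0420 each.

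Of 19 layer 5 subcerebral genes, 8 rose and 0 fell (9 and 1 adjusted over the list alone). Crim1, which marks corticospinal neurons, rose by 0.70 ± 0.036 on the log2 scale beside Fezf2. The list's camera adjusted p was 0.00477, and its call was lost at adjusted p = 0.0563 with an estimated correlation. Of 20 callosal and upper-layer genes, 4 rose and 6 fell (5 and 6 adjusted over the list alone), with a camera adjusted p of 0.719. Within that list Rorb, a nuclear receptor gene of layer 4, fell with a log2 fold change of -0.82 ± 0.057.

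Of 22 GABAergic postsynaptic genes, 9 rose and 2 fell (13 and 5 adjusted over the list alone). Gabrg1, a GABA-A receptor subunit gene, rose by 0.93 ± 0.088 on the log2 scale and Iqsec3, an ARF exchange factor of inhibitory synapses, by 0.54 ± 0.043. The list's camera adjusted p was 0.00246, against adjusted p = 0.0555 with an estimated correlation. Of 59 axon guidance genes, 19 rose and 10 fell (21 and 13 adjusted over the list alone). Netrin-G1, encoded by Ntng1, rose by 1.37 ± 0.092 on the log2 scale, the netrin receptor gene Unc5c by 0.68 ± 0.040 and the ephrin receptor gene Epha7 by 0.83 ± 0.074, whereas Cntn2, an axonal adhesion molecule, fell from 1007 ± 18.2 to 704 ± 24.6 CPM. The axon guidance call, at a camera adjusted p of 0.0233, was lost at adjusted p = 0.423 with an estimated correlation. 

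The next 6 lists were not called by camera. Of 37 glutamatergic synapse genes, 11 rose and 9 fell (14 and 9 adjusted over the list alone; camera adjusted p = 0.375). Among them the NMDA receptor subunit gene Grin3a rose from 78.6 ± 9.52 to 149 ± 12.4 CPM. Of 56 WNT signalling genes, 7 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.490). The ligand gene Wnt7b fell from 180 ± 10.5 to 79.2 ± 8.86 CPM and Lgr5, a receptor for R-spondins, rose from 0.583 ± 0.128 to 4.27 ± 0.748 CPM. Of 42 voltage-gated ion channel genes, 14 rose and 9 fell (16 and 11 adjusted over the list alone; camera adjusted p = 0.490), the sodium channel gene Scn2a1 with a log2 fold change of -0.42 ± 0.034. Of 23 cadherin genes, 9 rose and 6 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.0622). Of 43 autism risk genes, a list that holds Tbr1 and Scn2a1, 5 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.779). Its member Reln, which encodes a secreted glycoprotein that guides neuronal migration, fell from 549 ± 39.9 to 255 ± 6.95 CPM. Of 17 immediate early genes, 2 rose and 1 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.752). The WNT list had a median log2 fold change of -0.034, a mean of 0.00096 and a downward camera direction. The ion channel list had a median of -0.013, a mean of 0.0014 and an upward direction, and the autism list a median of 0.021, a mean of -0.014 and an upward camera but downward fry direction.

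Markers of other cell types were counted in the same way. Of 15 astrocyte markers, 7 rose and 1 fell (the same adjusted over the list alone), with the glutamate transporter gene Slc1a3 at 372 ± 8.56 CPM in null and 294 ± 24.6 CPM in WT. Of 20 interneuron markers, 1 rose and 6 fell (1 and 9 adjusted over the list alone), with the neuropeptide gene Sst at -0.50 ± 0.12. Of 14 vascular and blood markers, 0 rose and 4 fell (the same adjusted over the list alone), and of 15 dividing progenitor markers, 7 rose and 0 fell (the same adjusted over the list alone), with Neurod1, a transcription factor gene of newborn neurons, at 0.56 ± 0.053. The camera adjusted p was 0.0233, 0.00555, 0.00477 and 0.000773 for these 4 lists in that order. None of the 4 calls held, with adjusted p = 0.459, 0.135, 0.0563 and 0.155 with an estimated correlation. Oligodendrocyte lineage markers had 2 that rose and 6 that fell of 11 (4 and 6 adjusted over the list alone; camera adjusted p = 0.174), and 0 of 13 microglia markers were called by edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.635), with 2 at an unadjusted p under 0.05 and 0 called by DESeq2. The sex-linked list had 1 member past the edgeR filter, Xist, which was not called (camera adjusted p = 0.294), whereas DESeq2, with its own filter, called 4 members.

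Among called genes with a mean CPM of at least 5 and groups that did not overlap, the largest falls besides Drd1a were in Cyp26b1, which degrades retinoic acid, at 1.69 ± 0.601 against 16.6 ± 2.98 CPM, and in the melanocortin receptor gene Mc4r at -2.89 ± 0.16. The neurotrophin receptor gene Ngfr was at -2.10 ± 0.084 and the transcriptional repressor gene Bcl6 at -1.95 ± 0.094. The largest rises were in AI506816, at 11.3 ± 0.612 against 0.233 ± 0.0573 CPM, and in Hist1h2ba, at 10.6 ± 0.818 against 0.258 ± 0.0423 CPM. Hist1h2ba belongs to a histone gene family, and whether reads of other members were counted for it was not examined. The growth factor gene Fgf10 rose by 1.69 ± 0.14 on the log2 scale.

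Of 14588 genes tested, 2068 were called, 1067 higher and 1001 lower in null libraries, and 98 and 97 of these differed by over 2-fold. The median size of the log2 fold change among called genes was 0.31. The groups did not overlap in 2897 genes, or 19.9%, where chance gives 2.86% for independent libraries. With the paired libraries summed, 2 against 2, 479 genes were called, without Slc1a3 and Sst, limma with the pair as a random block called 1277, and 147 were called against a fold of 1.5 (glmTreat). Simulated groups with no effect, whose variation was shared within pairs, gave a mean of 732 calls and no overlap in 17.4% of genes (5 draws). Simulated libraries of a pair differed by sampling noise alone, and real ones by more. The 17.4% may thus be too high as a chance value.

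**Figure D2:**
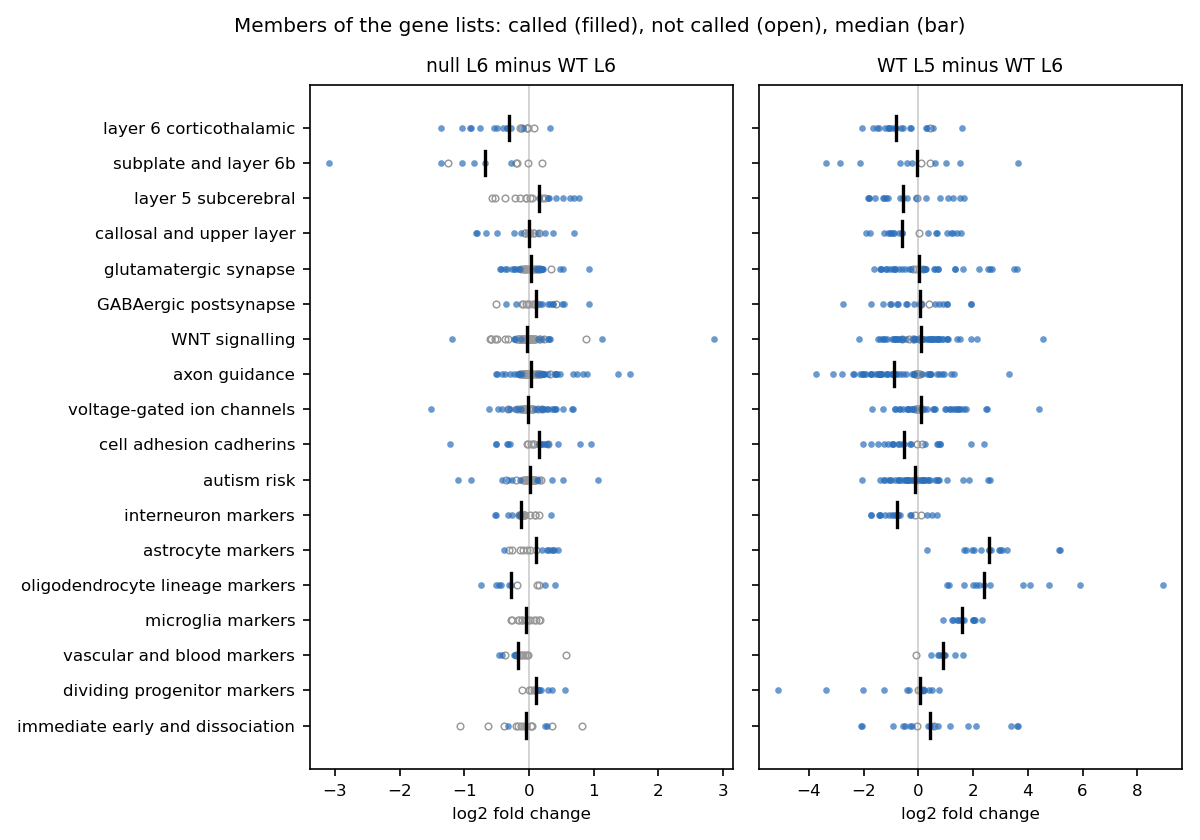
Log2 fold change of the measured members of 18 gene lists, null minus WT layer 6 in the left panel and WT layer 5 minus WT layer 6 in the right panel, with filled points for genes called at an adjusted p under 0.05, open points for the others and a bar at the median. The corticothalamic and subplate lists have medians of -0.31 and -0.68 in the left panel, and the astrocyte list has a median of 2.58 in the right panel.

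WT layer 5 libraries were compared with WT layer 6 libraries, which differ in layer by their labels and also in sequencing batch. Tbr1 was 4.14-fold lower in layer 5, at 42.6 ± 2.38 against 176 ± 7.07 CPM (n = 4 each). All 15 astrocyte markers, 13 oligodendrocyte lineage markers and 13 microglia markers were higher in layer 5. The astrocyte water channel gene Aqp4 was at 397 ± 5.62 against 11.1 ± 1.36 CPM, and the scaffold genes Shank1 and Shank3 were 11.4-fold and 6.18-fold higher. Lower in layer 5 were Neurog2, a proneural transcription factor gene, at 0.769 ± 0.187 against 26.9 ± 2.65 CPM, and Cntn2 at 75.1 ± 1.65 against 1003 ± 17.3 CPM. The edgeR adjusted p (Benjamini-Hochberg) was 4.25e-12 or less for the 30 genes picked by hand from the 96 that the naming rule gave, and the groups did not overlap for any of the 30. Here too both traits follow from the choice.

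Among the 15 astrocyte markers that rose, the glycolytic enzyme gene Aldoc stood at 838 ± 8.16 against 140 ± 4.85 CPM. The summed astrocyte markers were 11371 ± 51.6 CPM in WT layer 5, 2384 ± 122 CPM in WT layer 6 and 2662 ± 19.5 CPM in null layer 6 (n = 4 each). Outside the list, the receptor gene Gpr37l1 had a log2 fold change of 7.37 ± 0.069 and the mitochondrial glutamate carrier gene Slc25a18 one of 6.32 ± 0.12. All 13 oligodendrocyte lineage markers rose, among them the myelin gene Cnp at 3.82 ± 0.038 on the log2 scale. All 13 microglia markers rose, among them the receptor genes Csf1r at 1.46 ± 0.034 and Cx3cr1 at 2.02 ± 0.076. Of 13 vascular and blood markers, 12 rose and 0 fell, with the endothelial tight junction gene Cldn5 at 159 ± 5.47 against 62.7 ± 4.31 CPM. Counts adjusted over the list alone were equal for these 4 lists. The camera adjusted p was 2.23e-08, 1.86e-06, 3.38e-05 and 0.000320 in that order. With an estimated correlation, the astrocyte call was lost at adjusted p = 0.0904, and the others held at adjusted p = 0.0280, 0.0280 and 0.0375.

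Axon guidance genes were lower in layer 5, with 39 that fell and 13 that rose of 59 (the same adjusted over the list alone), at a camera adjusted p of 0.000149 and adjusted p = 0.0467 with an estimated correlation. Sema3c, a secreted semaphorin gene, had a log2 fold change of -3.12 ± 0.030, the semaphorin receptor gene Nrp1 one of -2.35 ± 0.025 and the adhesion molecule gene Chl1, from the same list as Cntn2, one of -2.01 ± 0.023. Of 20 interneuron markers, 15 fell and 3 rose (the same adjusted over the list alone; camera adjusted p = 0.00717, and adjusted p = 0.125 with an estimated correlation), with the transcription factor gene Lhx6 at -1.23 ± 0.034. Of 20 corticothalamic genes, 15 fell and 4 rose (the same adjusted over the list alone; camera adjusted p = 0.00988, and adjusted p = 0.257 with an estimated correlation). Nfib, a nuclear factor gene, fell from 927 ± 29.2 to 341 ± 3.41 CPM and Nxph3, which encodes a neurexophilin, from 48.3 ± 1.81 to 15.2 ± 0.785 CPM.

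Of 19 subcerebral genes, 6 rose and 12 fell in layer 5 (the same adjusted over the list alone; camera adjusted p = 0.168). Fezf2 was at 18.5 ± 0.652 against 66.3 ± 3.04 CPM, Crim1 had a log2 fold change of -1.09 ± 0.034 and Bhlhe22, a basic helix-loop-helix factor gene, one of -1.79 ± 0.029. Of 12 subplate genes, 4 rose and 6 fell (the same adjusted over the list alone; camera adjusted p = 0.850), with Nr4a2 at -2.85 ± 0.059. Rorb was 2.90-fold higher in layer 5, on a callosal and upper-layer list of which 8 rose and 11 fell of 20 (the same adjusted over the list alone; camera adjusted p = 0.759).

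The other lists were not called by camera in the layer comparison. Of 22 GABAergic postsynaptic genes, 8 rose and 10 fell (the same adjusted over the list alone; camera adjusted p = 0.887), with the receptor subunit gene Gabra2 at -2.74 ± 0.044. Of 37 glutamatergic synapse genes, 17 rose and 16 fell (17 and 18 adjusted over the list alone; camera adjusted p = 0.759). WNT signalling had 28 that rose and 22 that fell of 56 (the same adjusted over the list alone; camera adjusted p = 0.759), with Wnt7b at -1.23 ± 0.039. Voltage-gated ion channels had 21 and 14 of 43, cadherins 7 and 14 of 23, autism risk genes 18 and 24 of 43, and immediate early genes 10 and 7 of 19 (each the same adjusted over the list alone), at camera adjusted p of 0.205, 0.168, 0.563 and 0.759. Fos, an immediate early gene, rose from 1.23 ± 0.388 to 15.7 ± 0.527 CPM. Dividing progenitor markers had 6 that rose and 6 that fell of 15 (5 and 6 adjusted over the list alone; camera adjusted p = 0.759), with Eomes, a factor gene of intermediate progenitors, at 4.82 ± 0.351 against 50.1 ± 0.570 CPM. Of 5 sex-linked genes, 0 were called by edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.479), with 0 at an unadjusted p under 0.05 and 0 called by DESeq2. The GABAergic list had a median log2 fold change of 0.046, a mean of -0.069, a downward camera and an upward fry direction. Medians of 0.047 and 0.24 stood beside means of -0.68 and -0.079 for the progenitor and sex-linked lists, with a downward and an upward camera direction, and the autism list had an upward fry direction with a median of -0.14.

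Outside the lists, the neuropeptide gene Nts was 25.2-fold and Igfbpl1, a gene of immature neurons, 19.8-fold lower in layer 5. Of 14927 genes tested, 12768 were called, 6293 higher and 6475 lower in layer 5, with 2708 and 1414 over 2-fold. The groups did not overlap in 12122 genes, or 81.2%, where chance gives 2.86% for independent libraries and simulated groups with variation shared within pairs gave 16.7%. All layer 6 libraries were sequenced in batch A and all layer 5 libraries in batches B and C, so layer and batch cannot be told apart; with the batch B libraries alone 12223 genes were called and with those of batch C alone 12073. Against a fold of 1.5 (glmTreat), 6371 were called.

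Null layer 6 neurons were compared with WT layer 5 neurons to complete the pairs of groups. Tbr1 was 2.22-fold higher in null layer 6, at 94.0 ± 2.40 against 42.3 ± 2.36 CPM (n = 4 each). Fezf2 was at 113 ± 3.44 against 18.4 ± 0.637 CPM and Cntn2 had a log2 fold change of 3.22 ± 0.033. Aqp4 was 33.2-fold and Shank1 9.96-fold lower in null layer 6, and Drd1a stood at 2.03 ± 0.148 against 12.9 ± 0.802 CPM. The edgeR adjusted p (Benjamini-Hochberg) of these 6 genes was 1.03e-12 or less, and the groups did not overlap for any of them. Of 15013 genes tested, 12653 were called by edgeR, 6371 higher and 6282 lower in null layer 6, and the groups did not overlap in 11995 genes, or 79.9%, where chance gives 2.86% for independent libraries and the same simulation gave 17.0%. This comparison also crosses batches, with 11951 genes called against batch B alone and 11847 against batch C alone. Against a fold of 1.5 (glmTreat), 6364 were called.

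WT layer 5 libraries had higher glial markers and less Fezf2 than WT layer 6 libraries. A move towards them thus need not be a move towards layer 5 neurons. Whether null layer 6 libraries moved towards WT layer 5 libraries was examined over the 14480 genes tested in both comparisons with WT layer 6. Wnt7b and Cntn2 were lower than in WT layer 6 in both, and Fezf2, Crim1 and Rorb moved in opposite directions, with Fezf2 at 0.78 in null and -1.84 in layer 5. Of 1822 genes called in both, 1053 had the same direction, or 57.8%, where independent lists give 49.9%. Higher in both were 554 genes, against 429 given by independent lists, and lower in both were 499, against 447. Higher in null and lower in layer 5 were 389, against 472, and the converse held for 380, against 406. The 2 comparisons share the WT layer 6 libraries, and simulated groups with no effect gave a mean of 135 genes called in both, 134 of them in the same direction (5 draws). Shared controls thus favour the same direction. The simulated groups also lacked the difference between layers, so their counts give no expected value for 1822 or 1053. The covariance of the log2 fold changes across genes was 0.0374, against 0.0173 ± 0.00083 (SD, 20 draws) in simulation, a difference of 0.0200. Over the 11512 genes with a mean CPM of at least 5 it was 0.0173, against 0.00727 ± 0.00053 in simulation, a difference of 0.0101. Pearson's r was 0.124 and Spearman's rho 0.076 across genes, which are not independent replicates, against a simulated r of 0.494 and rho of 0.457. The simulation lacked the difference between layers, which widens the observed layer 5 fold changes. Its r and rho are therefore no reference for the observed values. The SD of its covariance is none either, since variation was also drawn for each gene on its own. Whether the covariance exceeds what shared controls give was thus not settled. With the WT layer 6 libraries split by pair, the covariance was -0.00142 when null was set against replicates 1 and 2 and layer 5 against 3 and 4, and 0.0401 the other way round. In the same splits, 48.4% and 60.8% of the genes called in both had the same direction, and 58.2% to 59.2% in the splits across pairs. Against layer 5 libraries of batch B alone and batch C alone the covariance was 0.0373 and 0.0375, and 57.7% had the same direction in each. Each layer 5 pair has 1 library in either batch, so the batches are not separate measurements and their closeness is no test of batch.

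**Figure D3:**
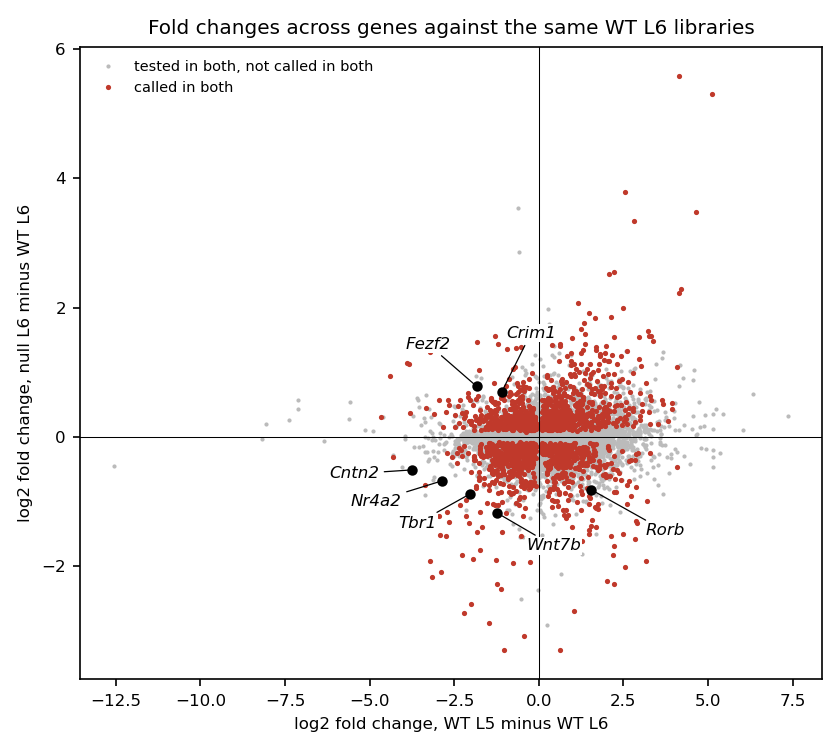
Log2 fold change of null minus WT layer 6 (vertical axis) against WT layer 5 minus WT layer 6 (horizontal axis), 1 point per gene tested in both, with the 1822 genes called in both in red and the others in grey. Tbr1, Nr4a2, Wnt7b and Cntn2 lie below 0 on both axes, and Fezf2, Crim1 and Rorb lie in the quadrants of opposite direction.

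TBR1 ChIP-seq of cortex at postnatal day 2 asked where in the genome the factor binds. The authors called peaks per replicate, in coordinates of the mouse build mm9. Replicate 1 against input gave 39756 summits in 34988 regions and replicate 2 gave 43517 in 38336. The region with the highest fold enrichment of the authors was on chromosome 5, at 147378757 to 147379845 in replicate 1 (63.3-fold) and 147378706 to 147379862 in replicate 2 (69.2-fold). The next were on mitochondrial DNA (M), at 10746 to 16299 with 57.4-fold and 1 to 6665 with 48.6-fold in replicate 1. In replicate 2 they were M at 10730 to 16299 with 59.6-fold and chromosome 5 at 146958586 to 146959781 with 55.4-fold. Each replicate list held only 177 distinct folds, each with 1 −log10 p, so the fold may not reflect the input at each site. With mitochondrial DNA among the highest, a high fold, or a region found in both replicates, need not mark TBR1 binding. No annotation of this build was used here, so genes at the peaks, Tbr1 included, are not named.

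Of the replicate 1 regions, 84.2% overlapped a replicate 2 region by at least 1 bp (95% Wilson interval 83.8 to 84.6, counting error only), where shifted copies gave a mean of 2.98% (100 draws). Of the replicate 2 regions, 76.5% (76.1 to 77.0) overlapped one of replicate 1, with 2.73% for shifted copies. The share rose with fold enrichment, from 63.2% to 99.7% between the lowest and highest of 4 equal bins of replicate 1 and from 48.4% to 99.2% in replicate 2. The list deposited under the blocking-peptide sample, whose peak names describe replicate 2 against a negative control, held 11665 summits in 10959 regions. At the 8953 summits it shares in position with replicate 2 against input, each of 167 folds of the authors in 1 list went with exactly 1 fold in the other, whereas replicates 1 and 2 shared 208 positions, with up to 10 folds for 1. That list thus holds replicate 2 signal and is not a separate measurement, so its overlap of 100% with replicate 2 is no comparison of samples. Of its regions 99.8% (99.7 to 99.8) overlapped replicate 1, with 2.58% for shifted copies, and 30.4% (29.9 to 30.9) of replicate 1 regions overlapped it. The list deposited under the IgG sample was identical to that of replicate 1 against input in all 39756 summits, so it is not a separate measurement. The median fold enrichment was 4.72 in replicate 1, 4.53 in replicate 2 and 5.54 in the blocking-peptide list, as the authors' values within each list. Chromosome X held 367 regions of replicate 1, or 2.21 per megabase, where autosomes held 11.4 to 18.8.

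**Figure D4:**
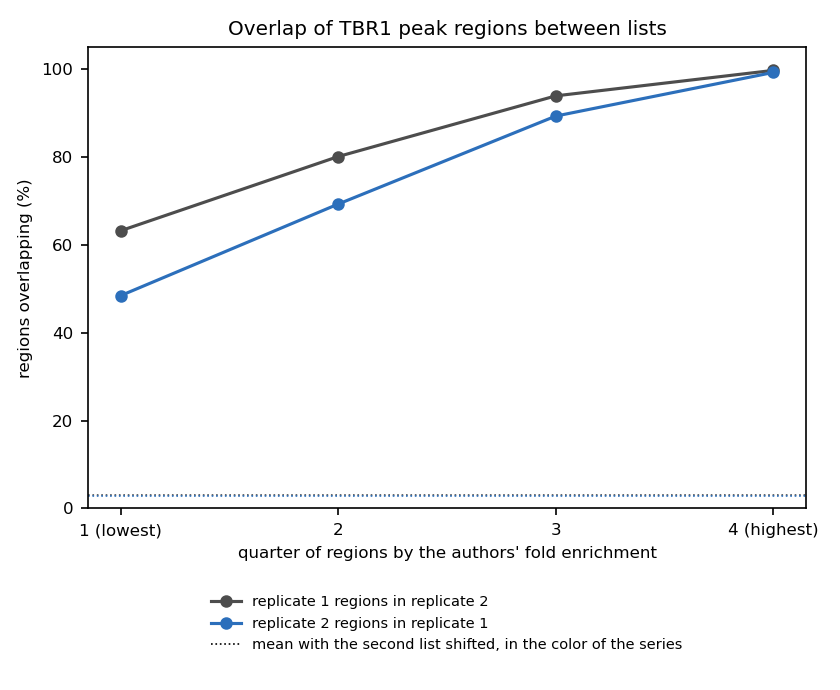
Percent of regions (vertical axis) that overlap the other list, in 4 equal bins of the authors' fold enrichment (horizontal axis), for replicate 1 in replicate 2 and replicate 2 in replicate 1, with dotted lines in the same colors at the means of shifted copies, 2.98% and 2.73%. In the highest bin 99.7% and 99.2% of the regions overlap.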

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

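The tests for a library that stands apart were set before the data were examined, whereas the 31 and 30 genes of the comparisons they ran on were picked after values were seen. Over 148 groups of 4 values, 3 had a highest or lowest library whose gap to the nearest other exceeded the critical value of Dixon's test, and chance gives such a gap in about 1 of 20 groups.

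Lars2, a gene for a mitochondrial leucyl-tRNA synthetase, was at 272.5 CPM in WT layer 6 replicate 4, with the other WT layer 6 libraries at 21.5 to 44.5 CPM. In null layer 6 it was at 77.2 to 2424 CPM, and it differed 1.85- to 7.09-fold within pairs of layer 6 libraries. The ribosomal RNA gene Rn45s was also highest in WT layer 6 replicate 4, at 0.723% of the counts against 0.384% to 0.443% in the other WT layer 6 libraries. In null layer 6 both genes were highest in replicate 4, with Rn45s at 2.67%. Ngfr was at 15.3 CPM in WT layer 6 replicate 3, with the others at 17.7 to 18.1 CPM, all above the null libraries. The summed oligodendrocyte lineage markers were at 1286 CPM in WT layer 5 replicate 3, with the others at 1296 to 1297 CPM. No explanation was tested for these 3 values.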

How the results depend on the processing

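Added after the data were seen were limma with the pair as a block, the summed pairs for layer 5 comparisons, lists and overlaps, fits without a pair of layer 6 libraries or without Rn45s, Lars2 and Mir6236, and the covariance without other cell type markers; all others were planned. Tbr1 kept its direction and call between null and WT layer 6 in every alternative (log2 fold change -0.94 to -0.84). The 2068 calls between null and WT layer 6 became 147 against a fold of 1.5 (fewer genes exceed it), 479 with pairs summed (478 of them among the 2068) and 1277 with the pair as a block. The last 2 allow for the pairing, with a consensus correlation of 0.41 within pairs. The main test takes libraries as independent, so its p-values and counts of calls leave the pairing out. Of the 92 genes the naming rule gave, 86 were called, none of which turned direction in any alternative; 51 lost their call against a fold of 1.5, 23 with pairs summed and at most 7 in any other. Among the 31 picked by hand, 10 lost their call against a fold of 1.5, Slc1a3 and Sst with pairs summed, and Sst with the replicate block and without WT or null replicates 1 and 2. Without 1 replicate the count was 1632 to 1838, for layer 5 against layer 6 12520 to 12850, and for null layer 6 against layer 5 12380 to 12688; a fold of 1.5 left 6371 and 6364 of the last 2. Other fits stayed within 1.5 times, among them DESeq2 with 2423 and 1506 without WT replicates 1 and 2. Such counts do not show whether the same genes were called. Without 1 replicate, 75.6% to 81.7% of the 2068 were called again in the same direction, and with the replicate block 71.9%. Replicate numbers do not pair the samples: correlations of same-numbered libraries were -0.080 to 0.024, 0 of 4, 1 of 4 and 3 of 4 matched their own number best in the 3 comparisons, and the replicate block gave 1526, 12675 and 12551 calls. Lists called went from 9 to 2 for null against WT with an estimated correlation, and from 7 to 4 for layer 5 against layer 6, or 15 with fry; the replicate block left 9 and 7. The covariance of 0.0374 was -0.00142 and 0.0401 with the WT layer 6 controls split by pair, 0.0269, 0.0334, 0.0253 and 0.0351 in the other splits, and 0.0173 at a mean CPM of at least 5; the cause was not tested. Genes called in both with the same direction went from 1053 to 830 and 808 in splits by pair, to 539, 537, 506 and 533 in splits across pairs and to 234 with pairs summed; the cause was not tested. Replicate 1 peak overlap of 84.2% became 80.6% at a −log10 q of at least 5, 76.8% at 50% of each region and 74.6% for the top 5000; replicate 2 gave 79.6%, 70.1% and 74.6%. The blocking-peptide list in replicate 1 gave 70.2% at 50% and 74.7% for the top 5000, and replicate 1 in that list 23.0%, 21.98% and 74.3%. Depth limits genes below a few CPM; Lgr5 was not tested at a mean CPM of at least 5. Tests of bound genes and of motifs, with their alternatives, were not run.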

Other observations

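Tests of Cajal-Retzius cell markers, of neighbouring genes, of cell types, stage and batch, and of pairs and sex were chosen after the results were seen; counts of other splits of the libraries were planned. Cajal-Retzius cells are early neurons of the cortical surface, and 7 of the 15 markers listed had been seen when the list was made. Against WT layer 6, 10 fell in null libraries, 2 rose and 3 were not called by edgeR, with a median log2 fold change of -0.89. Trp73, a p53-family factor gene, fell from 14.6 ± 1.77 to 3.88 ± 0.782 CPM (SD, n = 4 each), Ndnf, a secreted factor gene, from 45.8 ± 4.23 to 15.8 ± 1.46 CPM and Nhlh2 from 21.7 ± 2.46 to 9.23 ± 0.733 CPM. Ebf3 rose by 0.42 ± 0.12 and Emx2 by 0.30 ± 0.063 on the log2 scale. Among the 8 members not seen before, 4 fell and 2 rose, with an unadjusted limma camera p of 0.0243, or 0.0729 with an estimated correlation. In layer 5 against layer 6, 14 of the 15 fell and 0 rose, where 43.4% of all genes tested fell, with Nhlh2 at a log2 fold change of -2.95 and Reln at -0.42. Among the 8 members not seen before 7 fell there, with an unadjusted limma camera p of 0.00985, or 0.106 with an estimated correlation. The sort kept tdTomato-positive cells, and no source of these transcripts was tested.

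Genes next to Tbr1 were higher in null than in WT layer 6: of 20 tested neighbours 10 were called higher and 1 lower, where 1.47 higher are given by the genome-wide rate. Gcg rose by 3.28 ± 0.28, Ifih1 by 1.92 ± 0.18 and Fap by 1.401 ± 0.17 on the log2 scale, and 8 of the 10 were called with pairs summed. Chance position was tested by all 14138 windows of that size, a size set after the values were seen, and 0.0354% had as many, though 2 windows on chromosome 12 had 11. The 5 windows with as many include those centred on Tbr1 itself and on its neighbours Psmd14 and Ly75. Windows overlap, so they are not independent positions. A lower Tbr1 level alone may contribute, since 6 of the 9 measured in layer 5 are also higher there, but the genome-wide rate is 42.2% and the exact one-sided binomial p of 0.125, a check added after the result, leaves this open. DNA of another strain around the allele could also do so and stays open, as 1 neighbour, Cobll1, was lower and no genotype of these genes was analysed here.

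Layer 5 libraries had more glial transcripts and fewer transcripts of early neuronal stages than layer 6. A lower share of neurons alone was taken to raise other cell types alike. Medians rose by 2.58, 2.41, 1.58 and 0.898 on the log2 scale for astrocyte, oligodendrocyte lineage, microglia and vascular markers. The astrocyte and vascular medians differed by 1.68 (SE 0.275 and 0.0507), a test first run with interneurons in place of vascular markers. It cannot decide, because cell types that come along need not do so in equal shares in both sorts. A lower share of neurons and a different mix of cells stay open, although the sort was for tdTomato and all 15 astrocyte markers were also measured in layer 6. A later stage may contribute: of lists made after values had been seen, 16 of 18 earlier-stage genes fell, and 13 of 18 later-stage genes, or 72.2%, rose, short of the 75% set for it, where 43.4% of all genes tested fell and 42.2% rose. The unadjusted limma camera p was 3.66e-06 and 0.000628, or 0.00299 and 0.176 with an estimated correlation. In null against WT layer 6, 1 and 6 genes of these lists rose and 3 and 2 fell, where 7.31% of all genes tested rose and 6.86% fell. The unadjusted limma camera p there was 0.560 and 0.0249, or 0.552 and 0.313 with an estimated correlation. Sequencing batch stays open because 0 layer 6 libraries were in the batches of layer 5, and a difference between layers, which the design names, stays open too.

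Calls between null and WT layer 6 were weighed against the pairing and sex of the libraries. Simulated variation between pairs with no genotype effect gave at most 845 calls in 5 draws, below 2068. The simulation drew each gene on its own, so differences between pairs that move many genes together were left out. It therefore cannot decide how many of the calls stem from the pairs. Without WT replicates 1 and 2, the layer 6 libraries with 193 and 197 CPM of Y-linked genes, 61.0% of the calls were made again in the same direction among 6 libraries that all had Xist, so sex alone does not account for these. The WT arm is then 1 pair, so a difference of that pair stays open, and without WT replicates 3 and 4 the share was 69.6%. Of 35 splits of the 8 libraries, 1, the real one, called as many genes, with 36 the highest of the others. For layer 5 against layer 6 and null layer 6 against layer 5 it was also 1 of 35, with 0 the highest other. Such a share has its meaning only for independent libraries, and these were closest within pairs, so it does not exclude chance. Only 3 splits keep the pairs whole, which is too few for a share under 0.05 at the level of pairs.

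AI506816 and Hist1h2ba, the largest rises in null layer 6, were also higher in layer 5 than in WT layer 6, at log2 fold changes of 4.13 and 5.12.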
